A study of Homo sapiens with 54 samples.

How the data were processed

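RNA sequencing counts from 54 xenograft libraries were analysed. Per the labels, the tumours are castration-resistant prostate cancer (CRPC) xenografts, human tumour tissue grown in a host animal: the patient-derived lines LuCaP35, LuCaP70 and LuCaP96, and 22RV1, an established human prostate cancer cell line grown as a xenograft. The compounds are ORY-1001 (iadademstat) and GSK2879552, which inhibit the histone demethylase LSD1 (gene KDM1A), and I-BET762 (molibresib), which inhibits the BET bromodomain proteins. The series title frames the question as whether LSD1 inhibition disturbs super-enhancer activity; RNA alone was measured here.

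The labels describe 6 experiments, each with its own vehicle libraries. In LuCaP35, vehicle, ORY-1001 at 0.03 mg/kg 3 times per week, I-BET762 at 32 mg/kg 6 times per week and both together had 3 libraries each. 22RV1 had the same 4 groups with 4 libraries each. Other LuCaP35 experiments compared ORY-1001 at 0.06 mg/kg 3 times per week, or GSK2879552 at 33 mg/kg 6 times per week, with vehicle, with 3 libraries per group. GSK2879552 was given to LuCaP70 at 33 mg/kg 6 times per week (4 libraries per group) and to LuCaP96 at 15 mg/kg 3 times per week (3 per group). Doses and schedules therefore differ between the compounds and between tumours. The labels do not say that the replicates of a group are separate animals, so p-values measure only the spread between samples. They give no time on treatment, no sequencing batch and no tumour size.

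The deposited tables hold raw counts per gene, 57773 genes identified by Ensembl gene ID and symbol in 6 tables, 1 per experiment. Per the labels, RNA was extracted with the RNeasy Mini kit and libraries were made with the TruSeq Stranded Total RNA kit; the authors list FastQC 0.11.9, STAR 2.7.2 and featureCounts 1.6.4 with genome build hg19 (GRCh37). The strand setting, annotation release, handling of reads that map to several places and any removal of host reads are not given in the sources used here. Uncertain for that reason are counts of genes with near-identical copies (ribosomal protein genes and their processed copies, histone genes, AKR1C and UGT2B genes, mitochondrial genes and their nuclear copies, small structural RNAs), genes that overlap a neighbour and markers of other cells, which may hold host reads. All columns were whole numbers matched to samples by name, with 0 unused. Gene symbols turned into dates in some tables (29 of them) were restored by Ensembl ID; symbols shared by more than 1 ID (2234 IDs) were not used to match list members. Of the 66 pairs of libraries within a group, 0 were identical, and the correlation of log2 CPM (counts scaled by library size) within pairs was 0.969 to 0.997.

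Total counts per library were 1601480 to 19887382, a 12.4-fold range. In the LuCaP35 combination experiment they were 9493251 to 10059713 with vehicle, 6365267 to 8094178 with ORY-1001, 6867601 to 7810162 with I-BET762 and 5402429 to 7625821 with the combination, and in the same groups of 22RV1 they were 10164419 to 19887382, 6133185 to 12517037, 5679376 to 14803811 and 6495565 to 11421168. In LuCaP35 they were 10337258 to 17402429 (vehicle) and 13692272 to 15080393 (GSK2879552), and 13787569 to 17634614 (vehicle) and 13094476 to 16775025 (ORY-1001 at 0.06 mg/kg). LuCaP70 had 1651110 to 3300492 (vehicle) and 1601480 to 3138798 (GSK2879552), and LuCaP96 had 3914423 to 6460069 and 3194277 to 3727279. Vehicle libraries of the LuCaP35 combination experiment were all deeper than the treated ones.

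Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM scaling, robust quasi-likelihood fits and two-sided tests, with 1 fit per experiment and group as the only factor. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Of the 22 comparisons, 10 set a treatment against its vehicle, 4 set the combination against a single compound, 2 tested the interaction of ORY-1001 and I-BET762 (combination minus ORY-1001, less I-BET762 minus vehicle), and 6 tested the difference between effects of 2 experiments in a joint fit, in which the experiment and the tumour or compound cannot be separated. Log2 fold changes are treatment over vehicle, with the standard error (SE) of the fit. CPM values are group means ± SD on TMM-scaled library sizes, with n the number of libraries given above. The named genes follow a rule: 12 genes set for all treatment comparisons (among them KDM1A, FOXA1, HOXB13, MYC, KLK3, TMPRSS2, FKBP5, HEXIM1 and SERPINI1); up to 8 genes with the highest and 8 with the lowest log2 fold change (4 and 4 in the other comparisons) among changed genes with a mean CPM of 2 or more and no overlap between groups; and up to 4 members with the smallest p in lists that passed. The 12 set genes were added to the differences between experiments after values were seen. Clone names, pseudogenes, antisense and small RNAs were skipped, as were sex-linked marker genes; genes with a mean of 3 counts or fewer per library in a group, a limit set after values were seen, are not described by a fold. Some set genes, list members and lists are not reported here.

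Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and adjustment over the lists of a comparison; lists with fewer than 3 measured members were not tested. The 29 lists were written from general knowledge. Of these, 18 are programmes, among them prostate lineage transcription factors, LSD1-CoREST complex genes, BET inhibitor induced genes, MYC target nucleolar genes, E2F target replication genes, mitosis genes, p53 target genes, interferon-stimulated genes, neuroendocrine and neuronal genes, basal and squamous epithelial genes, epithelial-mesenchymal transition genes, hypoxia genes, cholesterol synthesis genes, unfolded protein and ATF4 response genes, and steroid metabolism genes. Another 6 are markers of other cells (fibroblast and matrix, endothelial, leukocyte, erythrocyte, skeletal muscle and adipocyte genes), and 5 concern sample quality (immediate-early genes, mitochondrially encoded mRNAs, ribosomal protein genes, small structural RNA genes and replication-dependent histone genes). For most lists the text also gives members changed when p-values were adjusted over the list alone, and camera with the correlation between genes estimated from the data. Of the 204 list calls over all comparisons, 2 held with an estimated correlation.

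Groups, comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Alternatives were RLE size factors, DESeq2 1.42.0 (Wald test), no filter, a filter at 1 CPM, a replicate term, each library left out in turn and, in the 4-group experiments, a fit of only the compared groups. A further alternative, offsets for the trend of each library with GC content and transcript length (splines with 5 degrees of freedom, from GENCODE 29 by Ensembl ID, which held 90.6% of IDs), was chosen after GC trends were seen, as were list tests without each library that stood apart from its group. Other analyses counted genes changed under other splits of the libraries, and compared the overlap of calls between compounds with simulated data. On simulated data edgeR recovered 57.6% to 95.3% of genes changed 4-fold and 1.54% to 22.2% of those changed 1.5-fold, across comparisons. The 1 to 23 false calls need not be a small share of the calls made. With a trend on GC content added to the simulated treated libraries and no offsets, false calls were 343 of 473 for ORY-1001 at 0.03 mg/kg in LuCaP35 and 435 of 559 in 22RV1, and with the offsets 6 of 113 and 4 of 108. GENCODE 29 (GRCh38) served only for gene type, GC content, transcript length and for leaving out Y-linked genes. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).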

Results

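In LuCaP35 the LSD1 inhibitor GSK2879552 lowered MYC, which encodes a growth-promoting transcription factor, and genes that set prostate identity, including FOXA1, HOXB13 and SOX9. Genes for DNA replication and cell division fell, among them the replicative helicase subunit MCM5 and the mitotic kinases PLK1 and AURKA. Genes that answer protein-folding stress rose, such as the endoplasmic reticulum chaperone HSPA5 and its cochaperone DNAJC3. SMOC1, which encodes a secreted matrix-associated protein, and SYT1, a gene of regulated vesicle release, rose, and GMNC, a regulator of multiciliated cells, and ELOVL2, a fatty acid elongase, fell. In total 4435 of 16585 genes changed with GSK2879552 at 33 mg/kg (2263 higher, 2172 lower, n = 3 libraries per group). The count was 2508 without vehicle replicate 3, 2683 without vehicle replicate 2 and 2871 without GSK2879552 replicate 1. Of the changed genes, 4379 had no overlap between the libraries of the groups; among all genes tested 44.1% had none, against the 10% that chance gives with 3 against 3.

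**Figure D1:**
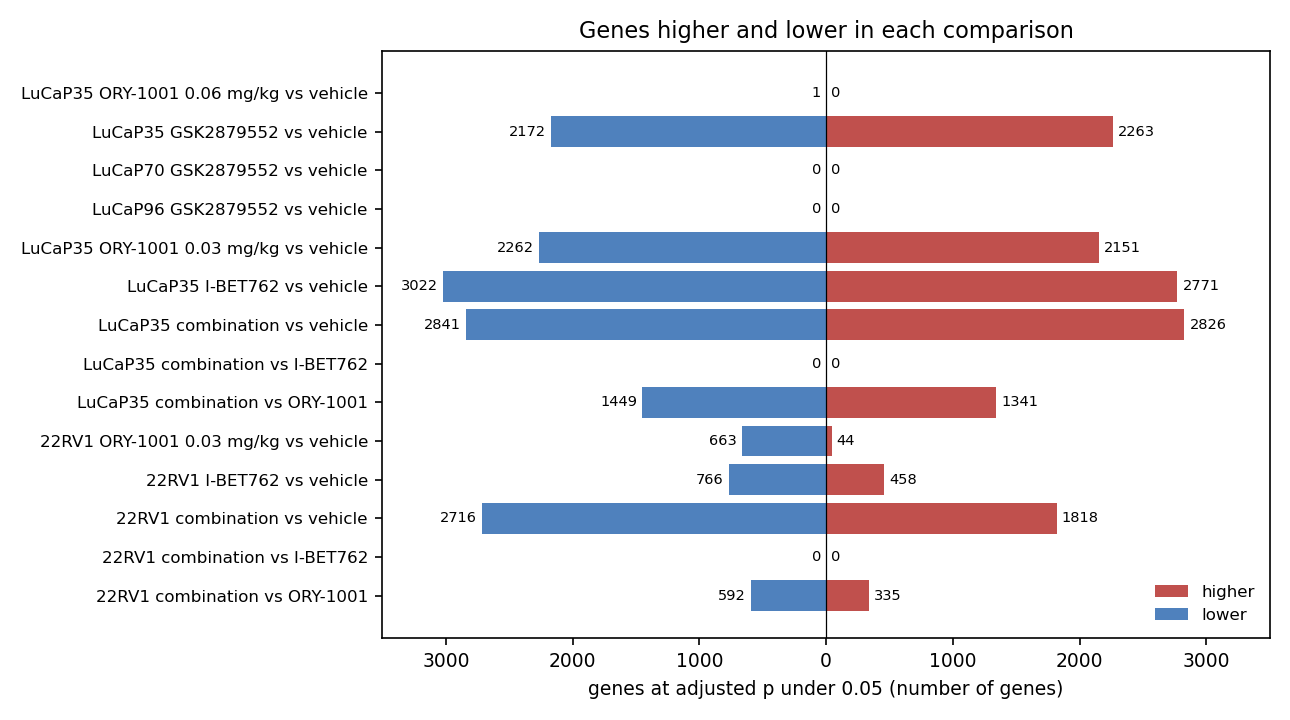
Number of genes higher and lower at an adjusted p under 0.05 (edgeR) in each of the 14 comparisons of 2 groups, as bars from 0. I-BET762 in LuCaP35 changed the most genes (5793), and 4 comparisons changed 0.

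MYC fell by 4.22 on the log2 scale with GSK2879552 (SE 0.38, adjusted p = 0.00119), from 123 ± 50.8 to 6.61 ± 1.68 CPM. The pioneer factor gene FOXA1 fell by 1.32 (SE 0.18, adjusted p = 0.00182) and HOXB13 fell by 0.73 (SE 0.09, adjusted p = 0.000326). TMPRSS2, a serine protease gene, fell by 0.55 (SE 0.1, adjusted p = 0.00256). These calls held without each library in turn. HEXIM1, which encodes an inhibitor of the elongation factor P-TEFb, rose by 0.61 (adjusted p = 0.0298), but its adjusted p was 0.105 without vehicle replicate 2, 0.0797 without vehicle replicate 3, 0.0878 without GSK2879552 replicate 1 and 0.092 without GSK2879552 replicate 2. SERPINI1, a neuroserpin gene used as a readout of BET inhibition, fell by 1.02 (adjusted p = 0.0149), with 0.0626 and 0.0777 without vehicle replicates 2 and 3 and 0.0603 without GSK2879552 replicate 1. KDM1A itself (log2 fold change -0.18, adjusted p = 0.111), KLK3 (-0.52, 0.264) and FKBP5 (0.16, 0.69) did not pass. SMOC1 had a log2 fold change of 3.07 (SE 0.31, adjusted p = 0.000159), SYT1 of 2.60 (SE 0.39, adjusted p = 0.000894), ELOVL2 of -3.63 (SE 0.44, adjusted p = 0.000315) and GMNC of -4.00 (SE 0.32, adjusted p = 5.78e-05).

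Of 54 measured E2F target replication genes, 37 fell with GSK2879552, 0 rose and 17 did not pass; adjusted over the list alone 46 were lower. Their median log2 fold change was -0.69 and camera gave an adjusted p = 3.99e-16, against adjusted p = 0.628 with an estimated correlation. MCM5 fell by 1.08 (SE 0.13, adjusted p = 0.000408) and UHRF1, a maintenance methylation factor, fell by 1.40 (SE 0.18, adjusted p = 0.000604). Among 50 mitosis genes 20 fell and 0 rose (25 lower when adjusted over the list alone; camera adjusted p = 2.3e-14, adjusted p = 0.629 with an estimated correlation), with PLK1 at -1.56 (SE 0.17, adjusted p = 0.000315). Among 45 MYC target nucleolar genes, which build ribosomes, 23 fell and 0 rose (29 lower adjusted over the list alone; camera adjusted p = 3.03e-07, adjusted p = 0.621 with an estimated correlation), including NOP16 at -0.84 (SE 0.1, adjusted p = 0.000301). The prostate lineage transcription factors had 12 of 23 lower and 1 higher (12 and 3 adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.621 with an estimated correlation), with SOX9 at -1.87 (SE 0.23, adjusted p = 0.000334).

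Of 31 unfolded protein and ATF4 response genes, 18 rose and 1 fell with GSK2879552 (19 and 2 adjusted over the list alone; camera adjusted p = 1.06e-06, adjusted p = 0.621 with an estimated correlation), with HSPA5 at 1.02 (SE 0.12, adjusted p = 0.000315) and DNAJC3 at 0.96 (SE 0.09, adjusted p = 9.87e-05). Among 24 cholesterol synthesis genes 12 fell and 0 rose (14 lower adjusted over the list alone; camera adjusted p = 0.00016, adjusted p = 0.628 with an estimated correlation), including EBP at -0.84 (SE 0.1, adjusted p = 0.000335). Of 7 measured basal and squamous epithelial genes 3 fell and 0 rose (6 lower adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.621 with an estimated correlation), with SFN, the gene of the 14-3-3 sigma protein, at -1.45 (SE 0.09, adjusted p = 1.22e-05). The 16 immediate-early genes had 6 lower and 1 higher, the same counts when adjusted over the list alone (camera adjusted p = 0.0415, lower, 0.083 with the GC offsets, adjusted p = 0.664 with an estimated correlation): the growth brake BTG2 fell by 1.98 (SE 0.18, adjusted p = 9.87e-05) and JUND rose by 1.00 (SE 0.12, adjusted p = 0.000311). Mitochondrially encoded mRNAs moved beside these groups, with 11 of 13 higher (camera adjusted p = 5.61e-07, adjusted p = 0.621 with an estimated correlation).

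The other LSD1 inhibitor, ORY-1001 at 0.06 mg/kg, lowered the lineage transcription factor list as a set in LuCaP35. FOXA1 and HOXB13 were among its members with the smallest p, though neither passed. MYC differed widely between libraries of the same group. Skeletal muscle, leukocyte and fibroblast markers were higher as sets in the same comparison. Of 17035 genes 1 changed (0 higher, 1 lower, n = 3). The number of changed genes was 176 without ORY-1001 replicate 2 and 20 without ORY-1001 replicate 3, and 0 without any of the other 4 libraries. In the fit of all libraries 1290 genes had an unadjusted p under 0.05, and DESeq2 called 158. FOXA1 had a log2 fold change of -0.81 (SE 0.12, adjusted p = 0.0802), and passed without ORY-1001 replicate 2 (-0.86, adjusted p = 0.00239) and replicate 3 (-0.72, adjusted p = 0.0444). HOXB13 (-0.59, adjusted p = 0.253), TMPRSS2 (-0.46, 0.264) and MYC (-1.70, 0.83; 242 ± 98.9 to 74.4 ± 89.2 CPM) did not pass, nor did KDM1A (-0.07, 0.936).

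Of 22 prostate lineage transcription factors, 1 fell with ORY-1001 at 0.06 mg/kg and 0 rose; adjusted over the list alone 8 were lower. Their median was -0.50, and camera gave an adjusted p = 9.1e-15, which held at adjusted p = 0.0307 with an estimated correlation. E2F target replication genes had 0 of 54 changed with a median of -0.23 (camera adjusted p = 1.49e-10, adjusted p = 0.599 with an estimated correlation). Mitochondrially encoded mRNAs had 0 of 13 changed and 13 higher when adjusted over the list alone (camera adjusted p = 9.1e-15, adjusted p = 0.558 with an estimated correlation). Beside these, 0 of 4 skeletal muscle genes changed with a median of 3.12 (camera adjusted p = 0.00562, adjusted p = 0.559 with an estimated correlation), 0 of 11 leukocyte genes (2 adjusted over the list alone) with a median of 0.65 (camera adjusted p = 0.00144, adjusted p = 0.558 with an estimated correlation) and 0 of 17 fibroblast and matrix genes with a median of 0.47 (camera adjusted p = 0.00562, adjusted p = 0.559 with an estimated correlation).

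Set side by side in LuCaP35, where dose and schedule differ, no single gene passed a test of the difference between the LSD1 inhibitors. As sets, mitosis and replication genes were higher with ORY-1001 at 0.06 mg/kg than with GSK2879552, and unfolded protein response genes lower. With edgeR 0 of 17849 genes passed the test of the difference (3283 at an unadjusted p under 0.05, 725 by DESeq2; smallest adjusted p 0.0656); the count was 219 without replicate 1 of the GSK2879552 vehicle, and 22, 2 and 1234 without ORY-1001 replicates 1, 2 and 3. MYC differed by 2.49 (SE 1.2, adjusted p = 0.309) and PLK1 by 1.35 (SE 0.25, 0.0656). Mitosis genes had 0 of 50 passing and 23 higher adjusted over the list alone (camera adjusted p = 1.05e-17, adjusted p = 0.773 with an estimated correlation), E2F target replication genes 0 of 54 passing and a median of 0.50 (camera adjusted p = 2.23e-10, adjusted p = 0.773 with an estimated correlation), and unfolded protein genes 0 of 31 and 13 lower (camera adjusted p = 4.54e-09, adjusted p = 0.773 with an estimated correlation).

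In LuCaP70, MYC and FOXA1 did not pass a test with GSK2879552. As sets, genes of mitosis were lower, and hypoxia, interferon-stimulated and immediate-early genes were higher. KLK3, which encodes prostate-specific antigen, had a lower mean without passing. With edgeR 0 of 12418 genes changed with GSK2879552 at 33 mg/kg (n = 4 per group), 944 had an unadjusted p under 0.05, and DESeq2 called 19; the smallest adjusted p was 0.533. These were the shallowest libraries, yet on simulated data at these depths edgeR recovered 91.7% of genes changed 4-fold and 57.1% of genes changed 2-fold. MYC was at 339 ± 33.1 CPM with vehicle and 290 ± 152 CPM with GSK2879552 (log2 fold change -0.23, adjusted p = 0.887), and KLK3 had -0.49 (0.642). Of 49 mitosis genes 0 changed and all 49 had a negative log2 fold change, with a median of -0.36 (camera adjusted p = 2.6e-16, adjusted p = 0.457 with an estimated correlation). All 30 hypoxia genes were positive with a median of 0.86, with 0 changed (camera adjusted p = 4.57e-12, adjusted p = 0.458 with an estimated correlation). Interferon-stimulated genes had 0 of 38 changed and a median of 0.66 (camera adjusted p = 2.06e-10, adjusted p = 0.458 with an estimated correlation), and immediate-early genes 0 of 15 (2 higher adjusted over the list alone) and a median of 1.18 (camera adjusted p = 4.55e-09, adjusted p = 0.457 with an estimated correlation). Fibroblast and matrix genes had a median of -0.38 with 0 of 16 changed (camera adjusted p = 0.00445, adjusted p = 0.457 with an estimated correlation). GSK2879552 replicate 1 stood apart on FOXA1 and replicate 4 on skeletal muscle markers. The 5 list calls given here held without either.

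In LuCaP96, given a lower dose on fewer days, 0 single genes changed with GSK2879552. Gene lists passed only with the preset correlation of camera. Ribosomal protein genes were lower as a set, and fibroblast, matrix and epithelial-mesenchymal transition genes were higher. The collagen gene COL1A1 led the fibroblast list without passing. HEXIM1 had a higher mean, also without passing. With edgeR 0 of 13717 genes changed at 15 mg/kg (n = 3), 1581 had an unadjusted p under 0.05, and DESeq2 called 67; without GSK2879552 replicate 1 the edgeR count was 3. The log2 fold changes followed transcript length (Spearman's rho 0.42 across genes); with the GC offsets the ribosomal, fibroblast and transition lists still passed (camera adjusted p = 1.8e-10, 1.58e-06 and 0.000411). HEXIM1 went from 118 ± 12.3 to 176 ± 13.3 CPM (log2 fold change 0.58, SE 0.19, adjusted p = 0.358), and MYC had -0.12 (0.964). All 54 ribosomal protein genes had a negative log2 fold change, with 0 changed and a median of -0.48 (camera adjusted p = 5.11e-16, adjusted p = 0.636 with an estimated correlation). Mitochondrially encoded mRNAs had a median of 0.98 with 0 of 13 changed and 13 higher adjusted over the list alone (camera adjusted p = 7.76e-11, adjusted p = 0.617 with an estimated correlation). Fibroblast and matrix genes had a median of 1.32, with 0 of 19 changed and 3 higher adjusted over the list alone (camera adjusted p = 4.09e-07, adjusted p = 0.617 with an estimated correlation), and COL1A1 had 2.34 (SE 0.41, adjusted p = 0.297). Epithelial-mesenchymal transition genes had a median of 0.99, with 0 of 15 changed and 1 higher adjusted over the list alone (camera adjusted p = 0.000176, adjusted p = 0.488 with an estimated correlation).

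The GSK2879552 effect differed between LuCaP70 and LuCaP35 for MYC, FOXA1, BTG2, SFN and THBS1, a matrix glycoprotein gene, which fell in LuCaP35 and did not pass in LuCaP70, and for PARM1, a mucin-like gene, which rose in LuCaP35. Of 15002 genes 232 differed (133 positive, 99 negative). The count was 34 and 35 without LuCaP35 vehicle replicates 2 and 3, 62, 61 and 132 without LuCaP35 GSK2879552 replicates 1 to 3, 51 without LuCaP70 vehicle replicate 4, and 420 and 350 without LuCaP70 GSK2879552 replicates 1 and 4. MYC differed by 3.96 (SE 0.58, adjusted p = 0.0117), with -4.22 in LuCaP35 and -0.23 in LuCaP70. BTG2 differed by 2.68 (SE 0.27, adjusted p = 2.58e-05), THBS1 by 2.68 (SE 0.32, adjusted p = 0.000283), SFN by 1.29 (SE 0.18, adjusted p = 0.00134) and PARM1 by -3.67 (SE 0.64, adjusted p = 0.0117; 2.96 in LuCaP35, -0.70 in LuCaP70). FOXA1 differed by 1.33 (SE 0.26, adjusted p = 0.0187), but not without LuCaP35 vehicle replicate 2 (0.0602) or 3 (0.0676). Prostate lineage transcription factors had 3 of 21 positive and 0 negative (10 and 1 adjusted over the list alone; camera adjusted p = 4.73e-05, adjusted p = 0.132 with an estimated correlation).

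**Figure D2:**
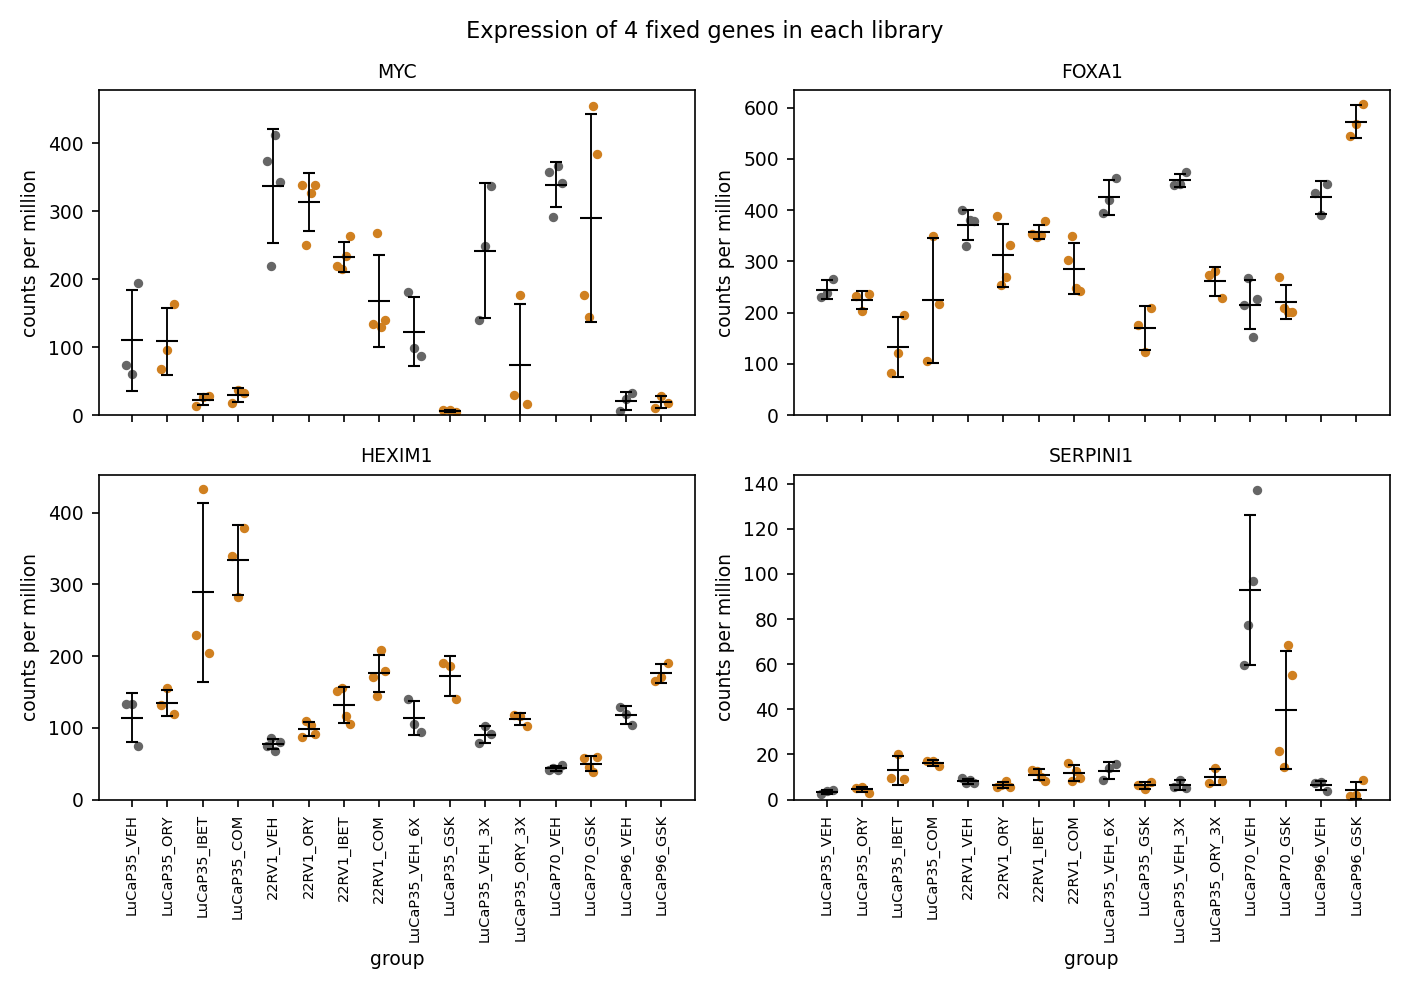
CPM of MYC, FOXA1, HEXIM1 and SERPINI1 in each library of the 16 groups (points), with bars for the group mean and lines for 1 SD; vehicle groups are grey and treated groups orange, and each axis starts at 0, so an SD that reaches below 0 is clipped. In the LuCaP35 GSK2879552 experiment MYC was at 123 ± 50.8 CPM with vehicle and 6.61 ± 1.68 CPM with treatment.

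ORY-1001 at the lower dose of 0.03 mg/kg changed many genes in LuCaP35, but MYC, FOXA1, KLK3 and KDM1A were not among them. Ribosomal protein genes and small structural RNAs such as RN7SK, the RNA scaffold that holds P-TEFb inactive, rose. Mitosis genes were lower as a set, with the checkpoint kinase BUB1B and the topoisomerase TOP2A among those that fell, and so did the mitochondrially encoded mRNA MT-ND4L. SGK1, a kinase gene induced by steroids and stress, and BST2, an interferon-stimulated gene, rose, and IQGAP2, a scaffold of the cell cortex, fell. In total 4413 of 15682 genes changed (2151 higher, 2262 lower, n = 3); the count was 2904 without ORY-1001 replicate 2, and 1810 with offsets for GC content and transcript length, of which 1371 were in both sets. The log2 fold changes followed GC content (Spearman's rho 0.51, and -0.44 with transcript length, across genes, which are not independent replicates).

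SGK1 had a log2 fold change of 1.90 with ORY-1001 at 0.03 mg/kg (SE 0.27, adjusted p = 0.000149), from 7 ± 1.29 to 26.2 ± 9.1 CPM, and TPGS1, a tubulin polyglutamylation subunit, of 2.26 (SE 0.32, adjusted p = 0.000154). IQGAP2 fell by 1.85 (SE 0.21, adjusted p = 4.7e-05; 85.3 ± 25.5 to 23.5 ± 2.96 CPM) and MTPN, which encodes myotrophin, fell by 1.98 (SE 0.21, adjusted p = 3.32e-05). These 4 calls held without each library and with the GC offsets. MYC had 0.00 (adjusted p = 0.996), FOXA1 -0.12 (0.858), KLK3 0.47 (0.388) and KDM1A -0.12 (0.462). Of 54 ribosomal protein genes 47 rose and 0 fell (50 higher adjusted over the list alone) with a median of 0.62 (camera adjusted p = 4.03e-24, adjusted p = 0.854 with an estimated correlation). Of 7 small structural RNA genes 5 rose (6 adjusted over the list alone; camera adjusted p = 5.74e-05, adjusted p = 0.854 with an estimated correlation), with RN7SK at 2.56 (SE 0.27, adjusted p = 4.03e-05). Of 13 mitochondrially encoded mRNAs 8 fell, adjusted over the list alone as well (camera adjusted p = 2.83e-05, adjusted p = 0.854 with an estimated correlation), with MT-ND4L at -1.32 (SE 0.12, adjusted p = 9.56e-06). Mitosis genes had 21 of 50 lower and 0 higher (22 lower adjusted over the list alone; camera adjusted p = 3.23e-06, adjusted p = 0.854 with an estimated correlation), including BUB1B at -1.34 (SE 0.25, adjusted p = 0.000845). E2F target replication genes had 13 of 54 lower (11 adjusted over the list alone; camera adjusted p = 0.00775, adjusted p = 0.854 with an estimated correlation). Interferon-stimulated genes had 10 of 49 higher, adjusted over the list alone as well (camera adjusted p = 0.00716, adjusted p = 0.854 with an estimated correlation). BST2 rose by 0.96 (SE 0.16, adjusted p = 0.000418), while the calls of HLA-B and HLA-C ended with the GC offsets (adjusted p = 0.325 and 0.242).

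Between the ORY-1001 experiments in LuCaP35, mitochondrially encoded mRNAs were higher as a set and ribosomal protein genes lower as a set at 0.06 than at 0.03 mg/kg, and RN7SK was lower. NBEA, a vesicle trafficking gene, and the ubiquitin ligase gene HERC3 were higher, and AGR3 and ADAT3, a tRNA deaminase subunit, lower. Of 16853 genes 1897 differed (959 positive, 938 negative), and 326 with the GC offsets. The count was 1256 without vehicle replicate 3, 909 and 1156 without ORY-1001 replicates 2 and 3 of the 0.03 mg/kg experiment, and 965 and 1189 without vehicle replicates 2 and 3 and 2971 and 1089 without ORY-1001 replicates 2 and 3 of the other. MT-ND4L differed by 1.89 (SE 0.16, adjusted p = 1.37e-06), NBEA by 2.44 (adjusted p = 0.002; 0.83 and -1.61), HERC3 by 2.31 (adjusted p = 0.00789; -0.13 and -2.44), AGR3 by -2.16 (adjusted p = 0.0128), ADAT3 by -2.15 (adjusted p = 0.00152; -0.56 and 1.57) and RN7SK by -2.74 (adjusted p = 0.002). Ribosomal protein genes had 27 of 54 negative (43 adjusted over the list alone; camera adjusted p = 8.46e-21, adjusted p = 0.61 with an estimated correlation) and mitochondrially encoded mRNAs 9 of 13 positive (11 adjusted over the list alone; camera adjusted p = 1.46e-13, adjusted p = 0.61 with an estimated correlation).

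I-BET762 lowered MYC in LuCaP35 and raised HEXIM1 and SERPINI1, genes known to answer BET inhibitors. Histone genes of the BET inhibitor induced list rose, and ribosomal protein genes rose as a block. Cell division genes and interferon-stimulated genes were lower as sets, with the RNA helicase gene DDX60 of the interferon list among those that fell. MAFA, a transcription factor of beta cells, and the mucin gene MUC6 rose, and the ligand WNT5A, the macrophage growth factor CSF1 and the epithelial differentiation factor ZNF750 fell. Of 15682 genes 5793 changed (2771 higher, 3022 lower, n = 3), and 4292 without vehicle replicate 3, the lowest count without any 1 library; with the GC offsets 3915 changed, 3034 of them in both sets. The log2 fold changes followed GC content and transcript length (Spearman's rho 0.35 and -0.42; 0.26 and -0.34 for the combination). MYC fell by 2.25 (SE 0.56, adjusted p = 0.0134), from 109 ± 74.1 to 22.8 ± 7.86 CPM; without vehicle replicate 3 it fell by 1.52 and still passed. HEXIM1 rose by 1.34 (SE 0.3, adjusted p = 0.00606; 114 ± 34.1 to 289 ± 125 CPM) and SERPINI1 by 1.91 (SE 0.32, adjusted p = 0.000342; 3.45 ± 1.04 to 13 ± 6.31 CPM). HOXB13 had -0.88 (adjusted p = 0.0346), with 0.148 without vehicle replicate 3 and 0.0579, 0.116 and 0.0935 without I-BET762 replicates 1, 2 and 3. KLK3 (1.01, adjusted p = 0.0601) and FOXA1 (-0.87, 0.125) did not pass. MAFA had a log2 fold change of 3.46 (SE 0.5, adjusted p = 0.000124), WNT5A of -3.60 (SE 0.54, adjusted p = 0.000174), CSF1 of -2.99 (SE 0.49, adjusted p = 0.00029) and ZNF750 of -2.82 (SE 0.32, adjusted p = 2.45e-05).

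Of 14 BET inhibitor induced genes 12 rose with I-BET762 in LuCaP35 and 0 fell, adjusted over the list alone as well, with a median of 1.07 (camera adjusted p = 2.98e-07, adjusted p = 0.56 with an estimated correlation). The histone gene HIST1H2BD rose by 1.75 (SE 0.25, adjusted p = 0.000171). All 54 ribosomal protein genes rose, or 44 with the GC offsets (median 0.76; camera adjusted p = 2.89e-27, adjusted p = 0.56 with an estimated correlation), and of 7 small structural RNA genes 6 rose (7 adjusted over the list alone; camera adjusted p = 3.3e-05, adjusted p = 0.56 with an estimated correlation). Mitosis genes had 36 of 50 lower and 1 higher (40 and 1 adjusted over the list alone; camera adjusted p = 2.34e-10, adjusted p = 0.824 with an estimated correlation), with BUB1B at -1.93 (SE 0.26, adjusted p = 6.12e-05), and E2F target replication genes 14 of 54 lower and 1 higher (camera adjusted p = 0.0132, adjusted p = 0.959 with an estimated correlation), with E2F8 at -3.03 (SE 0.44, adjusted p = 0.000162). Interferon-stimulated genes had 11 of 49 lower and 1 higher (10 and 1 adjusted over the list alone), a median of -1.20 (camera adjusted p = 6.15e-05, adjusted p = 0.955 with an estimated correlation) and DDX60 at -1.88 (SE 0.35, adjusted p = 0.000707). Prostate lineage transcription factors had 7 of 22 lower and 0 higher, adjusted over the list alone as well (camera adjusted p = 0.0216, adjusted p = 0.824 with an estimated correlation): the glucocorticoid receptor gene NR3C1 fell by 1.42 (SE 0.23, adjusted p = 0.000244) and the epithelial factor EHF by 2.21 (SE 0.42, adjusted p = 0.00297).

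ORY-1001 and I-BET762 shared many calls in LuCaP35 against the same vehicle libraries. With both, 1516 genes rose and 1610 fell (380 and 436 if the calls were independent), and 13 went opposite ways. Sharing a vehicle group ties the effects: in simulated data with unchanged treated groups the correlation of log2 fold changes was 0.47 (0.63 measured) and the covariance 0.042 (0.269). The simulation held no GC trend, on which vehicle libraries lay apart, so the excess need not be a shared response. With the GC offsets 1260 calls were shared.

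The combination in LuCaP35 raised SERPINI1, HEXIM1 and every measured BET inhibitor induced gene. TMPRSS9, a serine protease gene, and the histone gene HIST1H2BE rose, and the orphan nuclear receptor RORB and LRRC31, a leucine-rich repeat gene, fell. As sets, mitosis, interferon-stimulated and hypoxia genes were lower. CMPK2, a mitochondrial nucleotide kinase of the interferon response, and LOX, a collagen crosslinking enzyme, fell. In total 5667 of 15682 genes changed (2826 higher, 2841 lower, n = 3); the lowest count without 1 library was 4033, without vehicle replicate 3. SERPINI1 rose by 2.24 (SE 0.32, adjusted p = 0.000113; 3.45 ± 1.04 to 16.4 ± 1.27 CPM) and HEXIM1 by 1.55 (SE 0.3, adjusted p = 0.00303; 114 ± 34.1 to 334 ± 48.3 CPM). MYC fell by 1.89 (SE 0.56, adjusted p = 0.0271; 109 ± 74.1 to 29.7 ± 9.79 CPM), but without vehicle replicate 3 its log2 fold change was -1.17 (adjusted p = 0.0789) and without combination replicates 1, 2 and 3 the adjusted p was 0.0929, 0.0505 and 0.0668. TMPRSS9 had 3.46 (SE 0.27, adjusted p = 1.95e-06), and HIST1H2BE 3.54 (SE 0.41, adjusted p = 2.61e-05). RORB went from 4.12 ± 1.41 to 0.219 ± 0.196 CPM (adjusted p = 0.000556) and LRRC31 from 5.39 ± 1.12 to 0.428 ± 0.31 CPM (adjusted p = 0.000139).

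All 14 BET inhibitor induced genes rose with the combination in LuCaP35, with a median of 1.37 (camera adjusted p = 2.33e-10, adjusted p = 0.294 with an estimated correlation). Replication-dependent histone genes had 4 of 7 higher, adjusted over the list alone as well (camera adjusted p = 0.0151, 0.0669 with the GC offsets, adjusted p = 0.685 with an estimated correlation). All 54 ribosomal protein genes rose, or 50 with the GC offsets (camera adjusted p = 7.23e-28, adjusted p = 0.685 with an estimated correlation). Mitosis genes had 29 of 50 lower and 0 higher (38 lower adjusted over the list alone; camera adjusted p = 2.33e-10, adjusted p = 0.785 with an estimated correlation). Interferon-stimulated genes had 12 lower and 1 higher of 49 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000387, adjusted p = 0.785 with an estimated correlation), with CMPK2 at -3.20. Hypoxia genes had 10 lower and 4 higher of 32 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.785 with an estimated correlation), with LOX at -1.70 (SE 0.28, adjusted p = 0.000407). Lineage transcription factors had 6 of 22 lower and 0 higher (5 adjusted over the list alone; camera adjusted p = 0.0376, 0.0669 with the GC offsets, adjusted p = 0.785 with an estimated correlation), including the grainyhead factor GRHL2 at -1.63.

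**Figure D3:**
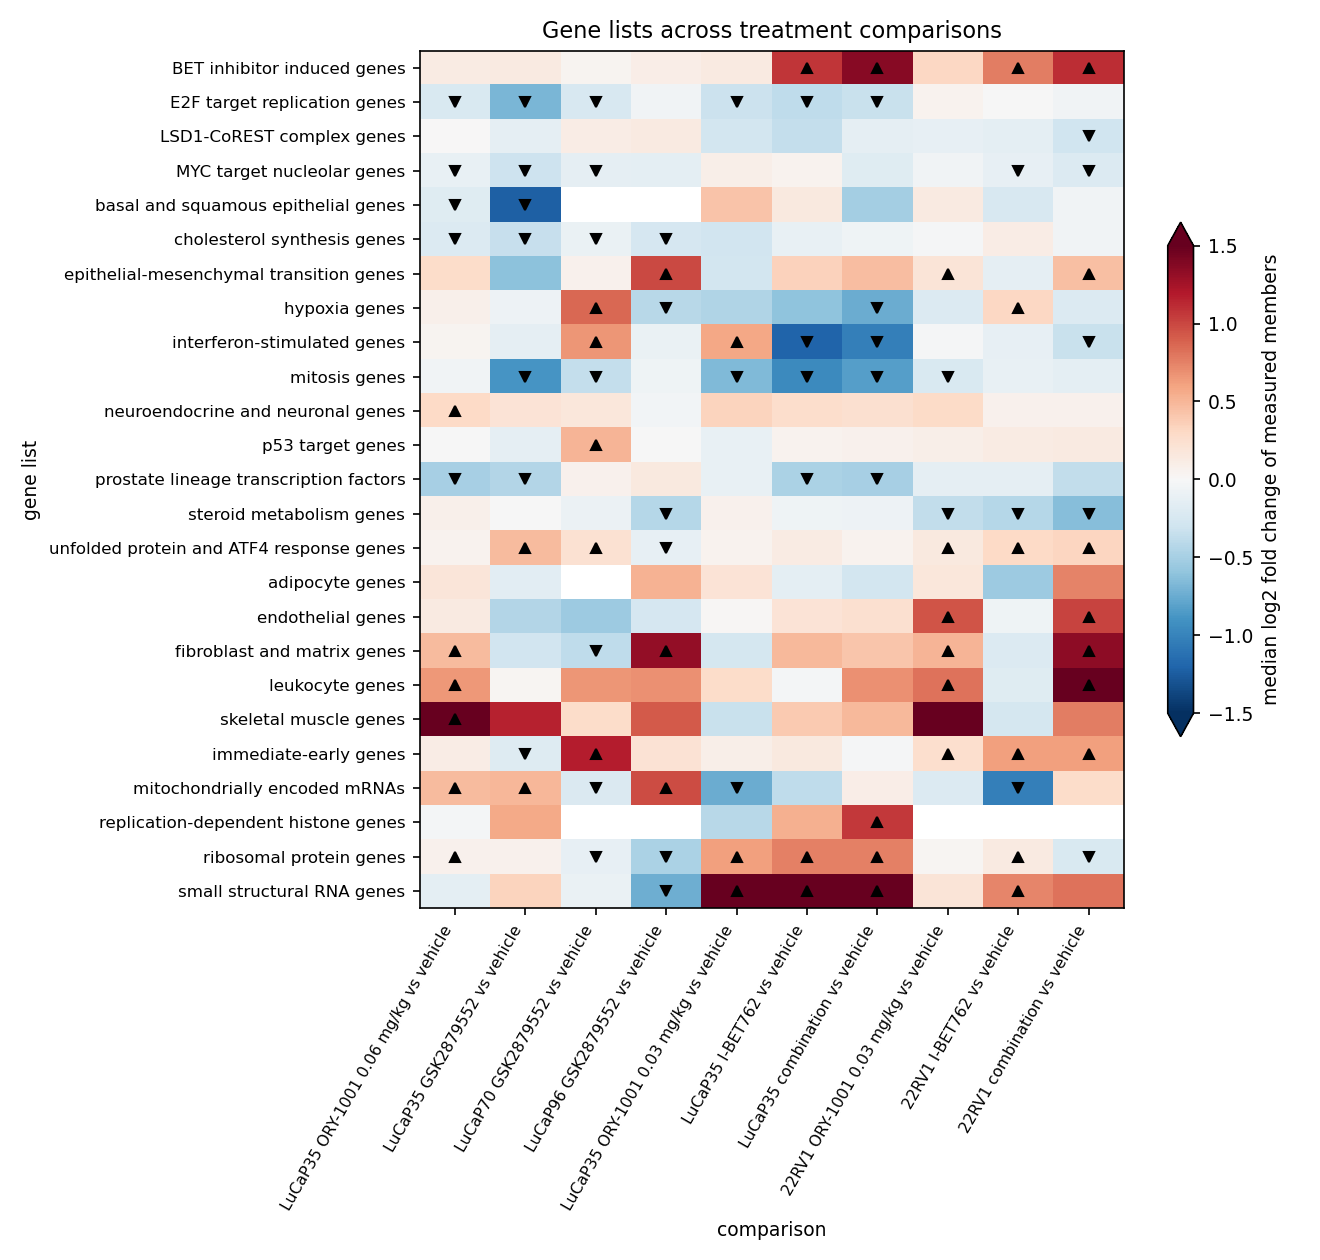
Median log2 fold change of the measured members of gene lists (vertical axis) in the 10 comparisons of a treatment with its vehicle (horizontal axis), as colour that saturates at 1.5 in either direction; triangles mark a camera adjusted p under 0.05 with the preset correlation, and white cells had fewer than 3 measured members. Ribosomal protein genes had a median of 0.76 with I-BET762 in LuCaP35 and -0.48 with GSK2879552 in LuCaP96.

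Against I-BET762 alone, the combination in LuCaP35 changed 0 single genes. BET inhibitor induced genes and mitochondrially encoded mRNAs were higher as sets, and MYC target nucleolar genes were lower. With edgeR 0 of 15682 genes changed (2054 at an unadjusted p under 0.05, 103 by DESeq2; smallest adjusted p 0.102); the count was 98 without I-BET762 replicate 2 and 185 without combination replicate 1. BET inhibitor induced genes had 0 of 14 changed (4 higher adjusted over the list alone) and a median of 0.32 (camera adjusted p = 0.00147, adjusted p = 0.678 with an estimated correlation), mitochondrially encoded mRNAs 0 of 13 changed (8 higher adjusted over the list alone; camera adjusted p = 7.43e-09, adjusted p = 0.678 with an estimated correlation) and MYC target nucleolar genes 0 changed (camera adjusted p = 1.25e-05, lower, adjusted p = 0.856 with an estimated correlation).

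Against ORY-1001, the combination in LuCaP35 lowered 25 of 49 interferon-stimulated genes and raised BET inhibitor induced histone genes. PSMB8, an immunoproteasome subunit, DDX60 and ATOH8, a basic helix-loop-helix factor, fell, and MAFA and HIST1H2BG rose. Mitochondrially encoded mRNAs rose. In total 2790 of 15682 genes changed (1341 higher, 1449 lower, n = 3), and 1409 without ORY-1001 replicate 3. Interferon-stimulated genes had 25 of 49 lower and 0 higher (36 lower adjusted over the list alone; camera adjusted p = 2.6e-15, adjusted p = 0.505 with an estimated correlation), PSMB8 at -1.12 (SE 0.14, adjusted p = 0.000181) and DDX60 at -2.33 (SE 0.37, adjusted p = 0.00104). BET inhibitor induced genes had 13 of 14 higher (camera adjusted p = 5.54e-13, adjusted p = 0.154 with an estimated correlation), with HIST1H2BG at 2.84. Mitochondrially encoded mRNAs had 13 of 13 higher (camera adjusted p = 4.07e-11, adjusted p = 0.441 with an estimated correlation). ATOH8 went from 12.3 ± 7.42 to 0.283 ± 0.0916 CPM (adjusted p = 0.000551), and MAFA had 3.61 (SE 0.54, adjusted p = 0.000809).

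The interaction asked whether the combination departed from the sum of both single effects in LuCaP35 on the log2 scale. As sets, mitochondrially encoded mRNAs and mitosis genes were above that sum, and ribosomal protein genes and small structural RNAs below it. NEU3, a sialidase gene, was above, and AGR3, a secretory pathway gene, below. The interaction passed for 3235 of 15682 genes (1664 positive, 1571 negative), and for 1054 with the GC offsets. MT-ND4L had an interaction of 1.95 (SE 0.16, adjusted p = 1.68e-05), NEU3 of 3.00 (adjusted p = 0.00336) and AGR3 of -3.41 (adjusted p = 0.00296). Ribosomal protein genes had 37 of 54 negative (42 adjusted over the list alone; camera adjusted p = 6.74e-17) and small structural RNA genes 5 of 7 (5; 5.18e-05). Mitochondrially encoded mRNAs had 8 of 13 positive (9; 3.46e-08) and mitosis genes 11 of 50 (12; 0.000153). With an estimated correlation adjusted p was 0.847 for mitosis genes and 0.589 for the rest.

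In 22RV1, far more genes were lower than higher with ORY-1001 at 0.03 mg/kg. GMFB, a glia maturation factor gene, TDRD6, a germline Tudor gene, and the kinetochore gene NUF2 fell, and ADM2, a peptide hormone of the adrenomedullin family, rose. MYC, HEXIM1 and KDM1A did not pass. Of 17443 genes 707 changed (44 higher, 663 lower, n = 4 per group), and 33 with the GC offsets, of which 29 were in both sets; the log2 fold changes followed GC content (Spearman's rho 0.62 across genes). The count without vehicle replicates 1 to 4 was 272, 83, 388 and 410, and without ORY-1001 replicates 1 to 4 it was 2134, 76, 3 and 31. GMFB had -1.60 (SE 0.25, adjusted p = 0.0053; 34.2 ± 9.4 to 11.1 ± 3.59 CPM), TDRD6 -1.54 (SE 0.26, adjusted p = 0.00675), NUF2 -0.95 (SE 0.16, adjusted p = 0.00675) and ADM2 0.90 (SE 0.15, adjusted p = 0.00675; 30.8 ± 1.57 to 57.6 ± 9.89 CPM). Without ORY-1001 replicate 3 their adjusted p was 0.0516, 0.0516, 0.0595 and 0.0516. MYC had -0.10 (adjusted p = 0.823), HEXIM1 0.35 (0.162) and KDM1A -0.21 (0.21). Mitosis genes had 7 lower and 0 higher (14 lower adjusted over the list alone; camera adjusted p = 0.0101, 0.299 with the GC offsets, adjusted p = 0.686 with an estimated correlation). Beside these, fibroblast and matrix genes had 0 of 21 changed and a median of 0.51 (camera adjusted p = 0.0312, higher, 0.0515 with RLE scaling, 0.11 without ORY-1001 replicate 2, adjusted p = 0.719 with an estimated correlation), and endothelial genes 0 of 11 and a median of 0.94 (camera adjusted p = 0.0247, 0.0723 with the GC offsets, 0.11 without ORY-1001 replicate 2, adjusted p = 0.677 with an estimated correlation). Skeletal muscle genes had 0 of 16 changed, with a median of 2.14 and a mean of 2.03 while the test pointed lower (camera adjusted p = 0.488). Without ORY-1001 replicate 2, which stood apart on these markers, they were lower as a set (camera adjusted p = 0.000345).

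I-BET762 raised HEXIM1 in 22RV1, together with stress-response genes such as DDIT3 and the immediate-early genes JUN and JUND. ADARB1, an RNA-editing enzyme gene, IRF7, a regulator of interferon genes, and the zinc-binding metallothionein MT1X rose. Some genes of steroid metabolism fell, including the ketosteroid reductase genes AKR1C1 and AKR1C2, as did CBLN4, a synaptic organiser, and SLC17A4, a phosphate transporter. MYC did not pass. Of 17443 genes 1224 changed (458 higher, 766 lower, n = 4), 37.4% of them higher; with RLE scaling 53.6% of 1310 were higher. With only the compared groups in the fit 2588 changed. The count was 411, 344 and 431 without vehicle replicates 1, 2 and 4, and 277 and 625 without I-BET762 replicates 2 and 4. HEXIM1 rose by 0.78 (SE 0.14, adjusted p = 0.00482), from 77.3 ± 7.24 to 132 ± 24.7 CPM, and MYC had -0.53 (SE 0.22, adjusted p = 0.134; 337 ± 83.6 to 233 ± 21.9 CPM). ADARB1 had 2.40 (SE 0.35, adjusted p = 0.00348), IRF7 1.40 (SE 0.18, adjusted p = 0.000416), SLC17A4 -2.69 (SE 0.3, adjusted p = 0.000129) and CBLN4 -2.13 (SE 0.22, adjusted p = 5.59e-05; 49.9 ± 7.57 to 11.4 ± 2.41 CPM). All held without each library in turn.

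BET inhibitor induced genes had 5 of 12 higher and 0 lower with I-BET762 in 22RV1 (8 higher adjusted over the list alone; camera adjusted p = 1.33e-06, adjusted p = 0.0602 with an estimated correlation). Unfolded protein and ATF4 response genes had 7 of 31 higher and 0 lower (12 adjusted over the list alone; camera adjusted p = 7.18e-07, adjusted p = 0.0602 with an estimated correlation), with DDIT3 at 0.98 (SE 0.16, adjusted p = 0.00329), and immediate-early genes 5 of 19 higher (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.18e-07, adjusted p = 0.0602 with an estimated correlation), with JUN at 1.04. Steroid metabolism genes had 6 of 18 lower and 0 higher (7 lower adjusted over the list alone; camera adjusted p = 0.000328, adjusted p = 0.0655 with an estimated correlation), with AKR1C1 at -1.25 (SE 0.19, adjusted p = 0.00241) and AKR1C2 at -1.32. MYC target nucleolar genes had 6 lower (8 adjusted over the list alone; camera adjusted p = 0.0228, 0.0755 with RLE scaling, adjusted p = 0.848 with an estimated correlation). Mitochondrially encoded mRNAs had 0 of 13 changed with a median of -1.03 (camera adjusted p = 0.000328, adjusted p = 0.691 with an estimated correlation).

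In 22RV1 the compounds shared fewer calls than in LuCaP35: 17 genes rose and 165 fell with both ORY-1001 and I-BET762, where 1.16 and 29.1 would if the calls were independent, which sharing a vehicle group prevents. The correlation of their log2 fold changes was 0.43 and the covariance 0.0885. In simulated data with unchanged groups, the same vehicle libraries and no GC trend they were 0.48 and 0.054. With the GC offsets 14 genes were called with both (1 higher, 13 lower). With a separate pair of vehicle libraries for each compound, over the 6 ways of pairing, 0 to 2 calls were shared and the correlation was 0.05 to 0.36. Few calls could be shared then: ORY-1001 had 0 to 73 and I-BET762 21 to 615.

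The combination in 22RV1 lowered MYC, HOXB13 and TMPRSS2 and raised HEXIM1. ADARB1 rose and SYT4, a synaptotagmin gene, CBLN4, SLC17A4 and the interferon-stimulated IFI44L fell. Steroid metabolism genes were lower as a set. The matrix-cell marker THY1 rose while DCN, a proteoglycan gene of the same list, fell. Of 17443 genes 4534 changed (1818 higher, 2716 lower, n = 4), 40.1% of them higher, or 51.8% with RLE scaling, and log2 fold changes followed GC content (rho 0.45; 0.39 with I-BET762); without combination replicate 3 the count was 2681. HEXIM1 rose by 1.19 (SE 0.14, adjusted p = 4.51e-05), to 176 ± 26.1 CPM, and MYC fell by 1.01 (SE 0.22, adjusted p = 0.00371), to 168 ± 66.9 CPM. HOXB13 fell by 0.88 (SE 0.22, adjusted p = 0.00774; 304 ± 70.9 to 165 ± 64.1 CPM) and TMPRSS2 by 1.16 (SE 0.26, adjusted p = 0.00499; 100 ± 5.55 to 44.8 ± 16 CPM). KDM1A had -0.30 (adjusted p = 0.025) and FOXA1 -0.38 (adjusted p = 0.0452), but with RLE scaling these were 0.0944 and 0.0957, and without combination replicate 3 they were 0.192 and 0.233. ADARB1 had 3.14 (SE 0.36, adjusted p = 0.000139; 27.5 ± 6.84 to 241 ± 54.4 CPM), SYT4 -2.93 (SE 0.33, adjusted p = 0.000117; 270 ± 38.2 to 35.1 ± 17.8 CPM), CBLN4 -3.21 (SE 0.24, adjusted p = 2.64e-07), SLC17A4 -3.77 (SE 0.33, adjusted p = 3.38e-06) and IFI44L -3.06 (SE 0.32, adjusted p = 2.17e-05).

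Steroid metabolism genes had 9 of 18 lower with the combination in 22RV1 (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000471, adjusted p = 0.0755 with an estimated correlation), with AKR1C1 at -1.85 (SE 0.2, adjusted p = 2.19e-05). LSD1-CoREST complex genes had 8 of 19 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0329, adjusted p = 0.501 with an estimated correlation). BET inhibitor induced genes had 7 of 12 higher (10 adjusted over the list alone; camera adjusted p = 1.26e-05, adjusted p = 0.0755 with an estimated correlation), immediate-early genes 8 higher and 1 lower (camera adjusted p = 6.17e-05, adjusted p = 0.0755 with an estimated correlation), and unfolded protein genes 10 of 31 higher (camera adjusted p = 0.000504, adjusted p = 0.235 with an estimated correlation). MYC target nucleolar genes had 18 of 45 lower and 0 higher (19 adjusted over the list alone; camera adjusted p = 0.00127, adjusted p = 0.532 with an estimated correlation), with WDR12 at -0.83, and interferon-stimulated genes 14 of 39 lower and 5 higher (camera adjusted p = 0.044, 0.0672 without combination replicate 2, adjusted p = 0.359 with an estimated correlation).

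Markers of other cells, which may hold host reads, also moved in the 22RV1 combination. Fibroblast and matrix genes had 5 of 21 higher and 2 lower (11 and 3 adjusted over the list alone), a median of 1.34 (camera adjusted p = 0.00125, adjusted p = 0.501 with an estimated correlation), THY1 from 0.172 ± 0.152 to 3.56 ± 1.72 CPM (adjusted p = 0.000119) and DCN at -1.87 (SE 0.24, adjusted p = 8.48e-05). Without combination replicate 4, in which COL1A1 was highest, 2 rose and 3 fell, the median was 0.91 and the camera adjusted p was 0.0282. Leukocyte genes had 4 of 13 higher and 1 lower (camera adjusted p = 0.0046) and endothelial genes 2 of 11 higher (camera adjusted p = 0.0292, 0.134 with the GC offsets). With an estimated correlation both had adjusted p = 0.501, and without combination replicate 4 camera gave 0.0637 and 0.114.

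**Figure D4:**
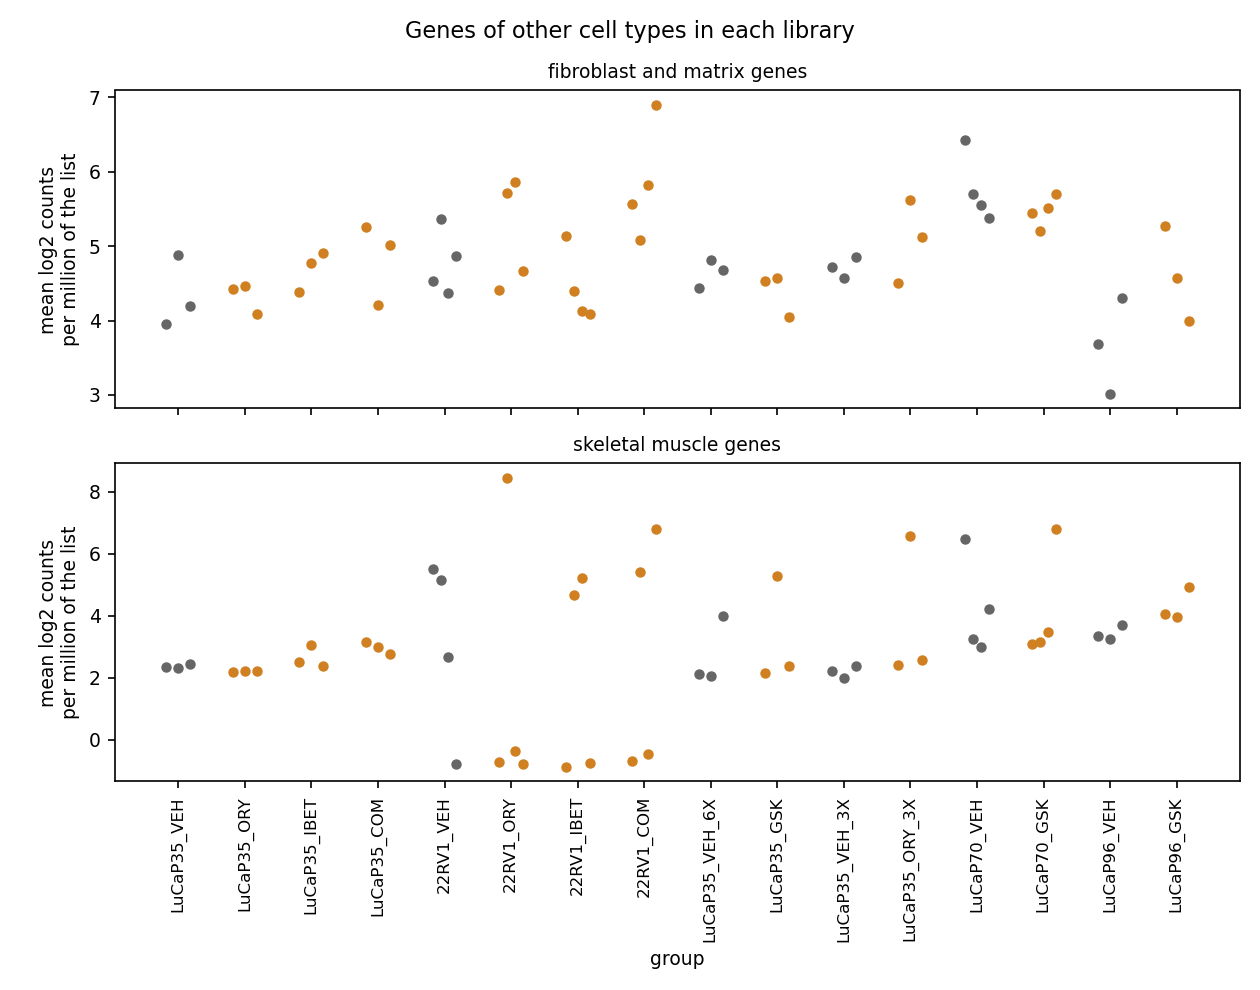
Mean log2 CPM of the fibroblast and matrix genes and of the skeletal muscle genes in each library (points), by group. The skeletal muscle mean of 22RV1 ORY-1001 replicate 2 was 8.45, and those of its group's other libraries were -0.77 to -0.36.

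Against I-BET762 alone, the combination in 22RV1 changed 0 single genes. Ribosomal protein genes were lower as a set, and fibroblast and mitochondrially encoded genes were higher. With edgeR 0 of 17443 genes changed (3163 at an unadjusted p under 0.05, 445 by DESeq2; smallest adjusted p 0.11), and at most 124 without 1 library, combination replicate 2. Of 54 ribosomal protein genes 0 changed and 33 were lower adjusted over the list alone (camera adjusted p = 3.39e-18, adjusted p = 0.367 with an estimated correlation). Fibroblast and matrix genes had 0 changed, 14 higher and 1 lower adjusted over the list alone, and a median of 1.93 (camera adjusted p = 9.22e-11, adjusted p = 0.367 with an estimated correlation), and mitochondrially encoded mRNAs had 0 of 13 changed (camera adjusted p = 4.58e-09, adjusted p = 0.367 with an estimated correlation).

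Against ORY-1001 alone, the combination in 22RV1 raised ADARB1 and HEXIM1 and lowered CBLN4 and AKR1C1. As lists, steroid metabolism genes were lower and p53 target genes higher. In total 927 of 17443 genes changed (335 higher, 592 lower, n = 4), 1646 with the GC offsets and 137 with only the compared groups in the fit. The count without ORY-1001 replicates 2, 3 and 4 was 570, 527 and 384, and without combination replicates 1 and 3 it was 462 and 373. ADARB1 had 2.56 (SE 0.35, adjusted p = 0.00202), HEXIM1 0.84 (SE 0.14, adjusted p = 0.00222), CBLN4 -2.28 (SE 0.23, adjusted p = 4.28e-05) and AKR1C1 -1.27 (SE 0.2, adjusted p = 0.00192). Steroid metabolism genes had 3 lower (6 adjusted over the list alone; camera adjusted p = 0.00126, adjusted p = 0.113 with an estimated correlation), and p53 target genes 3 higher and 0 lower (camera adjusted p = 0.00867, adjusted p = 0.217 with an estimated correlation).

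The interaction in 22RV1 passed for 0 single genes. Ribosomal protein genes were below the sum of the single effects as a set, and mitochondrially encoded and fibroblast genes above it. With edgeR 0 of 17443 genes passed (1617 at an unadjusted p under 0.05, 22 by DESeq2; smallest adjusted p 0.285), and 4 without ORY-1001 replicate 1. Ribosomal protein genes had 0 changed and 2 lower adjusted over the list alone (camera adjusted p = 1.14e-20, adjusted p = 0.692 with an estimated correlation), fibroblast and matrix genes 0 of 21 changed (camera adjusted p = 0.000738, adjusted p = 0.842 with an estimated correlation) and mitochondrially encoded mRNAs 0 of 13 (camera adjusted p = 2.4e-07, adjusted p = 0.692 with an estimated correlation).

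The ORY-1001 effect at 0.03 mg/kg differed between 22RV1 and LuCaP35 for EP300, the integrin gene ITGB1 and the cell cycle repressor E2F8, which fell in LuCaP35 and did not pass in 22RV1, and for RN7SK, which rose in LuCaP35. Ribosomal protein genes differed as a set. Of 19025 genes 679 differed (367 positive, 312 negative). The count was 415 and 350 without LuCaP35 vehicle replicates 2 and 3, 285, 343 and 242 without LuCaP35 ORY-1001 replicates 1 to 3, and 421 without 22RV1 vehicle replicate 3. EP300 differed by 1.46 (SE 0.24, adjusted p = 0.00401; 0.37 in 22RV1, -1.05 in LuCaP35), E2F8 by 2.06 (adjusted p = 0.00538), ITGB1 by 1.04 (adjusted p = 0.00553) and RN7SK by -1.81 (adjusted p = 0.0106). Of 54 ribosomal protein genes 10 were negative (33 adjusted over the list alone; camera adjusted p = 4.72e-21, adjusted p = 0.715 with an estimated correlation).

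With I-BET762, mitosis genes such as AURKA and CENPA, a centromeric histone, fell in LuCaP35 and did not pass in 22RV1, and WNT5A behaved likewise. AKR1C1 fell in 22RV1 alone, and VWCE, a secreted factor gene, fell in 22RV1 and rose in LuCaP35. The effects differed for 1013 of 19025 genes (533 positive, 480 negative), and for 583 and 552 without LuCaP35 I-BET762 replicates 1 and 2. CENPA differed by 1.69 (SE 0.28, adjusted p = 0.00122; 0.34 in 22RV1, -1.32 in LuCaP35), AURKA by 1.22 (adjusted p = 0.0024), WNT5A by 3.19 (adjusted p = 0.00254), VWCE by -3.54 (adjusted p = 1.6e-05; -0.90 and 2.66) and AKR1C1 by -1.78 (adjusted p = 0.00153; -1.25 and 0.56). Mitosis genes had 17 of 50 positive and 0 negative (30 adjusted over the list alone; camera adjusted p = 6.63e-18, adjusted p = 0.38 with an estimated correlation).

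With the combination, ribosomal protein genes as a set, FOXM1, a mitotic transcription factor, BUB1B, LOX and AKR1C1 differed between 22RV1 and LuCaP35. The receptor tyrosine kinase gene ROR2 rose in 22RV1 and fell in LuCaP35. The effects differed for 1495 of 19025 genes (620 positive, 875 negative; 41.5% positive, or 49.7% with RLE scaling), and for 950 without LuCaP35 combination replicate 1. ROR2 differed by 3.97 (adjusted p = 0.00122; 2.15 in 22RV1, -1.82 in LuCaP35), FOXM1 by 1.56 (adjusted p = 0.0013), BUB1B by 1.62 (adjusted p = 0.00184), LOX by 2.22 (adjusted p = 0.00436) and AKR1C1 by -2.12 (SE 0.31, adjusted p = 0.00011; -1.85 and 0.28). Of 54 ribosomal protein genes 53 were negative (54 adjusted over the list alone; camera adjusted p = 1.27e-43, adjusted p = 0.146 with an estimated correlation), and mitosis genes 14 of 50 positive (20 adjusted over the list alone; camera adjusted p = 1.2e-12, adjusted p = 0.618 with an estimated correlation).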

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

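Differences of the set genes between experiments, SERPINI1 among them, were added to the named genes after values were seen; no other test in this part was chosen after its result was seen. Among 106 tests for a library far from its group (groups of 4; chance picks out about 1 in 20), 6 stood apart. TMPRSS2 was at 109 CPM in 22RV1 vehicle replicate 2 (97.4 to 98 in the others). MYC was at 250 CPM in 22RV1 ORY-1001 replicate 2 (327 to 339) and 268 CPM in 22RV1 combination replicate 2 (129 to 140). FOXA1 was at 270 CPM in LuCaP70 GSK2879552 replicate 1 (201 to 210). The mean log2 CPM of skeletal muscle genes was 8.45 in 22RV1 ORY-1001 replicate 2 (-0.77 to -0.36) and 6.79 in LuCaP70 GSK2879552 replicate 4 (3.08 to 3.46).

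The other results here are effects that differed between experiments by the edgeR test of the difference. Between ORY-1001 doses in LuCaP35 1897 genes differed, with PLXNA4, an axon guidance receptor gene, at 2.7 and the ligand gene WNT11 at -2.96 (adjusted p = 0.0638 without ORY-1001 replicate 2 of the 0.03 mg/kg experiment). For GSK2879552 in LuCaP70 minus LuCaP35 it was 232 genes, with MYC at 3.96, FOXA1 at 1.33, PARM1 at -3.67 and PHLDA1, an apoptosis-linked gene, at 4.44. The adjusted p of PHLDA1 was 0.0892 and 0.0643 without LuCaP35 vehicle replicates 2 and 3, 0.0716, 0.0826 and 0.0645 without LuCaP35 GSK2879552 replicates 1 to 3, and 0.0521 and 0.0647 without LuCaP70 vehicle replicates 1 and 4. For ORY-1001 in 22RV1 minus LuCaP35 it was 679 genes, with HLA-DPB1, a gene of antigen presentation, at -3.12 (-0.84 without LuCaP35 ORY-1001 replicate 3, adjusted p = 0.536). The adjusted p of HLA-DPB1 was 0.0581 to 0.117 without any 1 of LuCaP35 vehicle replicates 1 to 3, 22RV1 vehicle replicates 1, 3 and 4 or 22RV1 ORY-1001 replicates 1 to 4. For I-BET762 it was 1013 genes, with the coagulation factor gene F3 at 3.59, SERPINI1 at -1.44 (0.45 in 22RV1, 1.91 in LuCaP35) and VWCE at -3.54. Without LuCaP35 vehicle replicates 1 and 2, LuCaP35 I-BET762 replicate 2 and 22RV1 vehicle replicates 1 and 3 in turn, the adjusted p of SERPINI1 was 0.0829, 0.0567, 0.15, 0.0574 and 0.0547. For the combination it was 1495 genes, with ROR2 at 3.97 and SERPINI1 at -1.70 (0.53 in 22RV1, 2.24 in LuCaP35).

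In 40 seeded regroupings of the libraries, the real one included, 1 reached the count for the difference between ORY-1001 doses (1897). This excludes chance only against draws that mixed the groups of both experiments: the highest other, 1896, kept or mirrored the real groups of 1 experiment, so the count does not show that the doses differ. Chance cannot be excluded for LuCaP70 minus LuCaP35 (4 reached 232; highest other 2119), nor for ORY-1001 (2 reached 679; highest other 1624), I-BET762 (3 reached 1013; highest other 2507) and the combination (5 reached 1495; highest other 4857) in 22RV1 minus LuCaP35. For ORY-1001 at 0.06 mg/kg minus GSK2879552 the real count was 0, which all 40 reach by construction, so nothing about chance is tested (highest other 3100). In all of these differences, draws that mixed the groups of both experiments called at most 1 gene. Counts above the real one came only from draws that kept or mirrored a whole experiment.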

How the results depend on the processing

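The offsets for GC content and transcript length, and list tests without libraries that stood apart, were the alternatives chosen after results were seen. With RLE scaling and with the stricter filter of 1 CPM, all 22 counts of changed genes stayed within 1.5 times the value reported; with DESeq2 10 of 22 did, with no filter 14, with the GC offsets 16, and with only the compared groups in the fit 8 of 10. For named genes, 0 of 1147 values reversed direction with RLE scaling, with the replicate term or with the GC offsets, 0 of 1125 with DESeq2 and 0 of 1137 with the stricter filter; named genes were not refitted with no filter or with only the compared groups. Leaving out a library ended calls in 868, made calls in 173 and reversed 0 of 10469 values. The causes of the moved counts below were not tested, beyond what each setting's construction changes.

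With DESeq2 the count was 158 for ORY-1001 at 0.06 mg/kg in LuCaP35 (reported 1), 19 for GSK2879552 in LuCaP70 (0), 67 in LuCaP96 (0), 103 for the combination against I-BET762 in LuCaP35 (0), 1353 for ORY-1001 in 22RV1 (707), 2138 for I-BET762 in 22RV1 (1224), 445 for the combination against I-BET762 in 22RV1 (0) and 22 for the interaction in 22RV1 (0). For differences between experiments it was 725 for ORY-1001 at 0.06 mg/kg minus GSK2879552 (0), 877 for GSK2879552 in LuCaP70 minus LuCaP35 (232), and 1472 (679) and 1745 (1013) for ORY-1001 and I-BET762 in 22RV1 minus LuCaP35. With no filter on low counts these became 343 for ORY-1001 at 0.06 mg/kg, 168 in LuCaP70, 266 in LuCaP96, 320 and 29 for the combination against I-BET762 in LuCaP35 and 22RV1, 2 for the interaction in 22RV1, 1031 for ORY-1001 minus GSK2879552 and 729 for LuCaP70 minus LuCaP35.

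With the GC offsets the count was 10 for ORY-1001 at 0.06 mg/kg, 1810 and 33 for ORY-1001 at 0.03 mg/kg in LuCaP35 and 22RV1, 1054 for the interaction in LuCaP35, 1646 for the combination against ORY-1001 in 22RV1 and 326 for the difference between ORY-1001 doses. Calls shared by ORY-1001 and I-BET762 went from 3126 to 1260 in LuCaP35 and from 182 to 14 in 22RV1, or to 529 in 22RV1 at an adjusted p under 0.1. With only the compared groups in the fit, I-BET762 in 22RV1 changed 2588 genes and the combination against ORY-1001 in 22RV1 137. Gene lists passed camera 204 times, 2 times with an estimated correlation and 75 times with fry, which asks whether a list moves rather than whether it moves more than other genes. Of 608 list tests, RLE scaling ended 6 calls and made 3 (3 ended for ORY-1001 in 22RV1), the replicate term ended 4 and made 6, and the GC offsets ended 25 and made 24. Without 22RV1 ORY-1001 replicate 2, 4 of 9 list calls ended and 2 were made, and without LuCaP70 GSK2879552 replicates 1 and 4 it was 2 and 0 of 13 that ended.

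A term for replicate number moved 5 of 22 counts: 39 for ORY-1001 at 0.06 mg/kg, 3 in LuCaP96, 1 for the combination against I-BET762 in LuCaP35, 191 for ORY-1001 minus GSK2879552 and 143 for LuCaP70 minus LuCaP35. The labels do not say that equal numbers pair libraries. Correlations of residuals between equal numbers were over 0.1 in 3 of 18 and 7 of 24 pairs of the LuCaP35 and 22RV1 combination experiments, 1 of 3, 0 of 3, 1 of 4 and 1 of 3 pairs of the LuCaP35 GSK2879552, LuCaP35 ORY-1001, LuCaP70 and LuCaP96 experiments, and 0 of 12, 0 of 16, 3 of 6, 3 of 6, 3 of 8 and 2 of 6 libraries correlated best with their own number, so the samples were taken to share only a number.

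Leaving out 1 library at a time gave 0 to 176 genes for ORY-1001 at 0.06 mg/kg, 2508 to 4206 for GSK2879552 in LuCaP35, 0 to 3 in LuCaP96, 2904 to 3609 for ORY-1001 at 0.03 mg/kg in LuCaP35, 0 to 185 for the combination against I-BET762 and 1409 to 2273 against ORY-1001 in LuCaP35. In 22RV1 it gave 3 to 2134 for ORY-1001, 277 to 1181 for I-BET762, 2681 to 4758 for the combination, 0 to 124 for the combination against I-BET762, 373 to 1254 against ORY-1001 and 0 to 4 for the interaction. The differences between experiments ranged from 0 to 1234 for ORY-1001 minus GSK2879552, 909 to 2971 between ORY-1001 doses, 34 to 420 for LuCaP70 minus LuCaP35, and 242 to 727, 552 to 1224 and 950 to 1948 for ORY-1001, I-BET762 and the combination in 22RV1 minus LuCaP35. LuCaP70, with the shallowest libraries, had the fewest genes past the filter (12418), and on simulated data at the depths of LuCaP70 and LuCaP96 57.1% and 23.4% of genes changed 2-fold were recovered.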

Other observations

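The offsets for GC content and the test of a lower share of tumour RNA were chosen after results were seen.

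Of the GSK2879552 calls in LuCaP35, 67.4% had the same sign with ORY-1001 at 0.06 mg/kg and 37.2% at 0.03 mg/kg. GSK2879552 gave 62.7% in LuCaP70 and 63.4% in LuCaP96. In 22RV1, 80.5% of LuCaP35 I-BET762 calls (83% in reverse) and 77.2% of ORY-1001 calls at 0.03 mg/kg kept their sign. A shared GC trend could add to this. Genes are not independent, so no p is given.

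ORY-1001 at 0.03 mg/kg called 4413 genes in LuCaP35. Library depth is argued against as the cause, since 87.9% of calls were left in libraries thinned to the smallest total (87.2% to 88.8% over 5 draws). GC content and length bias stays open: 31.1% of calls were left with the offsets, between the bounds set beforehand, and mean correlations with GC content were -0.41 for vehicle and 0.37 for ORY-1001. A response seen at both doses stays open too, as 56.4% of calls had the same sign at 0.06 mg/kg (64.5% of the genes called with and without offsets). Bias and response cannot be told apart here, because all vehicle libraries lie on 1 side of the GC trend.

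More genes were lower than higher with ORY-1001 in 22RV1. Library depth is argued against, with 69.7% of calls left after thinning (59.4% to 72.4%). With the offsets 4.1% of calls were left, which met the bound set beforehand for GC content and length bias. All vehicle libraries lay below all ORY-1001 libraries in their correlation with GC content (-0.65 to -0.34 against -0.28 to 0.55). Bias and response therefore cannot be told apart, and the offsets could remove either. With them GMFB went from -1.60 to -0.99 (adjusted p = 0.0269) and ADM2 from 0.90 to 0.69 (adjusted p = 0.0324). No biological explanation was tested beyond the treatment itself.

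Fibroblast and matrix genes were higher with the combination in 22RV1. Stromal RNA in 1 library stays open. Without combination replicate 4 the list passed with the preset correlation (camera adjusted p = 0.0282), but with 2 members higher and 3 lower. A lower share of tumour RNA stays open: the medians of the fibroblast, endothelial and leukocyte lists differed by 0.71, too little to exclude a common rise and too much to show one. Host reads were not tested.

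Other splits of the compared libraries test chance. With 3 libraries per group the 10 splits are too few to tell: real and highest other counts were 1 and 0 for ORY-1001 at 0.06 mg/kg, 4435 and 0 for GSK2879552 in LuCaP35, 0 and 1 in LuCaP96, and in the LuCaP35 combination experiment 4413 and 0 (ORY-1001), 5793 and 0 (I-BET762), 5667 and 0 (combination), 0 and 8 (combination against I-BET762) and 2790 and 0 (against ORY-1001). In 22RV1, of 35 splits only the real one reached its count for I-BET762 (1224; highest other 1) and the combination (4534; 2), which argues against chance. It was also highest for ORY-1001 (707; 429) and the combination against ORY-1001 (927; 830). Chance stays open there, as leaving out 1 library moved these by more than that margin (3 to 2134 and 373 to 1254). Splits cannot tell treatment from GC bias. In LuCaP70 (highest other 2) and for the combination against I-BET762 in 22RV1 (1) all 35 reach the real count of 0, so chance is not tested. Of 100 regroupings, 1 reached the 3235 genes of the LuCaP35 interaction (highest other 720), and all 100 reach the 0 of the 22RV1 interaction, with 186 in another, which points to a structure of the samples.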
